A study of Homo sapiens with 12 samples.

How the data were processed

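Gene expression was measured by sequencing of polyadenylated RNA from 12 libraries of BEAS-2B cells kept for 20 weeks in 0.25 µM K2Cr2O7. Per the labels' protocols, total RNA was extracted with Trizol and mRNA was selected with oligo(dT) beads. The libraries formed 4 groups of 3: vehicle (0.05% DMSO), kava (25 µg/ml), and vehicle cells 48 h after transfection with 100 nM control siRNA or SNRPA1 siRNA. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and DESeq2 with genome build hg38, and do not say which steps apply to which table.

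The vehicle and kava table holds TPM values as deposited, with 78932 genes. The authors' name for that table mentions salmon, whereas the submitters' processing notes name HISAT2 and StringTie, and this difference could not be resolved. Each TPM column sums to 1000000, so depth cannot be read from it and no counting error can be given. The siRNA table, with 35697 genes, holds raw read counts and FPKM values per the file headers and the submitters' processing notes. The FPKM values were scaled by the authors for transcript length and library size, and 1 FPKM column lacks the FPKM prefix in its header and was assigned by its position. The count columns as deposited summed to 64384362, 65108896 and 65385258 for control siRNA replicates 1 to 3 and to 64672979, 61739821 and 55003534 for SNRPA1 siRNA replicates 1 to 3. The tables share 35185 gene identifiers and no library, and were tested apart.

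Kava was compared with vehicle by limma 3.58.1 in R 4.3.3, with eBayes and a mean-variance trend on log2(TPM + 1), over the 13866 genes with a mean of at least 1 TPM in the 6 libraries. SNRPA1 siRNA was compared with control siRNA by the quasi-likelihood test of edgeR 4.0.16 with TMM scaling, over the 13772 genes with a mean of at least 1 CPM. The plan, fixed before the data were examined, named limma for normalised values and edgeR where a table holds counts. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The SE of an edgeR fold change was taken as its size over the square root of its F statistic. A fitted SNRPA1 change is given for each comparison first, as a check of the labels.

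Genes are named by a rule fixed before the data were examined. It takes SNRPA1, and the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 and groups that do not overlap, leaving out clone names and LOC, LINC, MIR, SNOR, RNU and antisense genes. It also takes up to 4 called members of each fixed gene list, or the 2 with the highest mean if none was called. For the overlap it takes up to 10 genes higher in both comparisons, 10 lower in both and 5 changed in opposite directions. COL3A1, PDGFRB, PTPRC, SCGB1A1 and THY1, and CDH5 with kava, fall outside the rule and were chosen after their values were seen.

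The 28 biology lists cover U2 snRNP and branch-site factors, other snRNP proteins, the Prp19 complex and catalytic-step factors, SR proteins and hnRNPs, targets of NRF2, the aryl hydrocarbon receptor, p53 and ATF4, metallothioneins and zinc transporters, homologous recombination, G1/S, G2/M, endoplasmic reticulum chaperones, heat shock proteins, cholesterol, interferon-stimulated genes, NF-kB and cytokines, epithelial, mesenchymal and stemness genes, methylation enzymes, serine and one-carbon metabolism, glycolysis and hypoxia, oxidative phosphorylation, lysosome and autophagy, immediate early genes, apoptosis and ribosomal proteins. The 7 check lists cover mitochondrially encoded mRNAs, histones, nuclear or non-polyadenylated RNAs, and markers of fibroblasts, blood cells, endothelium and differentiated airway epithelium. Lists with at least 5 tested members were tested against the other genes by limma's camera with its preset correlation of 0.01, adjusted over the biology lists and over the check lists apart. Camera with an estimated correlation and fry were run as alternatives. Camera with an estimated correlation also uses far fewer degrees of freedom, those left by 6 libraries. A call lost in it thus need not have been lost to correlation between genes. The Prp19 list of the knockdown had an estimated correlation of -0.0261, under the preset 0.01. Its unadjusted p still rose from 3.68e-05 to 0.00965 (limma camera). Overlap of calls was tested with Fisher's exact test. Gene Ontology terms given in the siRNA table, with 15 to 300 tested members, were tested by camera in the same way.

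Positions of genes and transcript features came from GENCODE 29 on hg38. Tested genes in order along each chromosome were grouped in windows of 100, and window medians were set against 1000 random gene orders. Genes past the last full window of a chromosome were in no window, also where they adjoin a shifted one. Windows, Gene Ontology terms and the corrections for GC content and transcript length were not part of the plan fixed before the data were examined. Alternatives included other pseudocounts, filters and scalings, limma on FPKM, DESeq2 1.42.0, the replicate number as a block, and leaving out each library in turn. On simulated data with the spread of these libraries, the kava test recovered 22.4%, 67.2% and 90.9% of genes changed by 0.25, 0.5 and 1 on the log2 scale, with 6.25% of its calls false. The knockdown test recovered 0%, 4.48% and 56.1%, with 6.98% of its calls false. In both, a shifted list was called and 0 of 20 unchanged lists were called at an adjusted p under 0.05 by limma's camera. The simulated genes varied independently of each other, so this result does not cover lists whose members vary together. In the measured libraries the estimated correlation was 0.983 for the ribosomal list of the knockdown. The FPKM columns were used for alternatives alone, and no sample column was left out.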

Results

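RNA sequencing was carried out on BEAS-2B cells, an immortalised line of human bronchial epithelial cells, that had been kept for 20 weeks in 0.25 µM potassium dichromate, a source of hexavalent chromium [Cr(VI)], a lung carcinogen. The 12 libraries fell into 4 groups of 3. In the kava experiment, cells exposed to Cr(VI) together with 25 µg/ml kava, an extract of the plant Piper methysticum, were set against cells exposed to Cr(VI) and the vehicle, 0.05% DMSO. In the knockdown experiment, Cr(VI) and vehicle cells were transfected with 100 nM of an siRNA pool against SNRPA1 or of a non-targeting control siRNA and collected after 48 h. SNRPA1 encodes the A' protein of the U2 small nuclear ribonucleoprotein (U2 snRNP), which takes part in recognising the branch site of introns. The title of the series links kava, its component DHM and chromium-induced transformation to this splicing factor, and the comparisons address which transcripts differed with kava and which with loss of SNRPA1. Kava libraries were measured as TPM, transcript levels scaled to a sum of 1000000 in each library, so their depth is unknown. The siRNA libraries held 55003534 to 65385258 counted reads each. Levels are means ± SD of 3 libraries (n = 3), in TPM for kava and in CPM, reads per 1000000 counted after TMM scaling, for the knockdown, and log2 fold changes are given ± SE. The labels do not say whether replicates were separate cultures, so p-values of single genes measure the spread between these libraries.

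SNRPA1 was lower in both experiments. The gene, ENSG00000131876, lies on the minus strand of chromosome 15 from 101281510 to 101295282 (hg38). In control siRNA replicates 1, 2 and 3 it stood at 67.5, 58.8 and 60.1 CPM, and in SNRPA1 siRNA replicates 1, 2 and 3 at 21.3, 20.9 and 23.7 CPM. The means were 62.1 ± 4.68 and 21.98 ± 1.499 CPM, a 2.83-fold lower level (log2 fold change -1.499 ± 0.0980, edgeR adjusted p = 0.00495). With any 1 of the SNRPA1 siRNA libraries left out, the edgeR adjusted p lay between 0.0501 and 0.0558. In the kava experiment the vehicle libraries held 153, 152 and 147 TPM and the kava libraries 124, 127 and 130 TPM. With kava the mean fell from 151 ± 3.17 to 127 ± 2.99 TPM (log2 fold change -0.24 ± 0.0359, limma adjusted p = 0.00227), so that the level with kava was 0.846 of that with vehicle. The knockdown and kava values come from tables normalised apart and were not tested against each other.

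**Figure D1:**
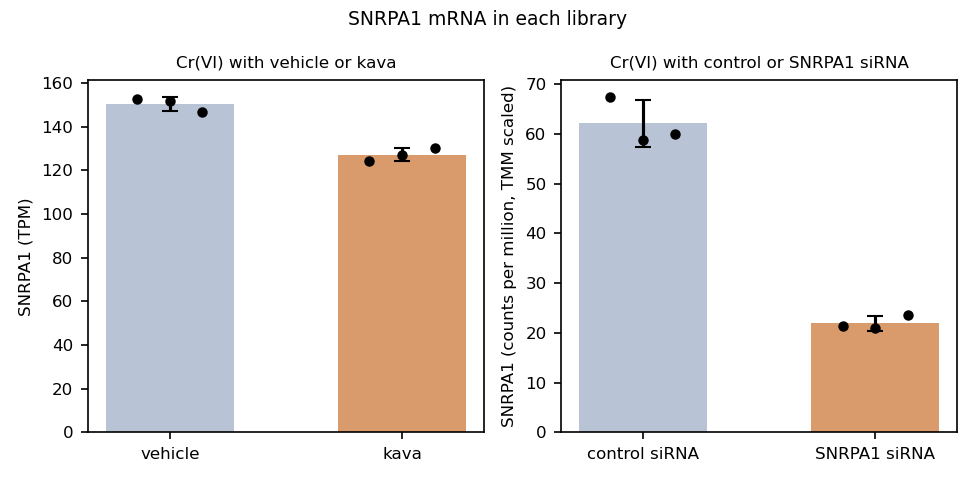
SNRPA1 mRNA in each library, in TPM for vehicle and kava (left) and in CPM for control and SNRPA1 siRNA (right); points are libraries, and bars and error bars are means and SD of 3 libraries. The kava libraries lay between 124 and 130 TPM, all under the vehicle libraries, and the SNRPA1 siRNA libraries between 20.9 and 23.7 CPM, all under the control siRNA libraries.

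With kava, the axon guidance receptor ROBO1 rose from 0.422 ± 0.277 to 29.7 ± 7.41 TPM (log2 fold change 4.42 ± 0.193, limma adjusted p = 1.05e-05) and the secretory granule protein PTPRN from 0.133 ± 0.0173 to 17.4 ± 1.47 TPM (4.02 ± 0.0863). The small heat shock protein HSPB8 rose by 3.41 on the log2 scale, to 12.2 ± 1.87 TPM, and glutamine synthetase, GLUL, by 3.38, to 15.2 ± 1.27 TPM. The collagenase MMP1 rose from 6.08 ± 0.647 to 40.1 ± 1.76 TPM (2.54 ± 0.0749). DPYSL3, which acts on the neuronal cytoskeleton, rose by 2.53 and HCLS1, a cortactin relative of blood cells, by 2.41. DUXAP8, DUXAP9 and DUXAP10 also stood among the largest rises, at 2.58, 2.51 and 2.50, but they are near-identical pseudogene copies and their separate values are uncertain.

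The largest fall with kava was that of the epithelial keratin KRT19, from 23.5 ± 1.18 to 0.705 ± 0.0309 TPM (log2 fold change -3.85 ± 0.0687, limma adjusted p = 6.83e-07). RIPOR3 fell from 20.8 ± 1.25 to 1.57 ± 0.154 TPM (-3.09). The ectoenzyme BST1 fell from 11.0 ± 0.743 to 0.436 ± 0.216 TPM (-3.08) and the membrane-bound transcription factor MYRF from 22.8 ± 1.12 to 3.37 ± 0.189 TPM (-2.45). ISYNA1, which makes inositol phosphate from glucose 6-phosphate, fell by 2.40 and the metallothionein MT1M by 2.14. The natriuretic peptide gene NPPB fell by 2.12, the homeobox gene HOXC8 by 1.72 and AP1M2, an adaptor of epithelial sorting, by 1.67. BOLA2B fell by 1.83, an uncertain value because the gene has a near-identical copy.

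In all, 4429 of 13866 tested genes changed with kava (31.9%; limma adjusted p under 0.05), 2261 higher and 2168 lower. Most changes were small, with a median absolute log2 fold change of 0.33 among the changed genes, and 151 rose and 57 fell by at least 2-fold. The 3 kava values lay wholly above or below the 3 vehicle values in 47.2% of tested genes, where chance gives 10%. Fold changes are on the scale of log2(TPM + 1), which understates the change of low genes.

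**Figure D2:**
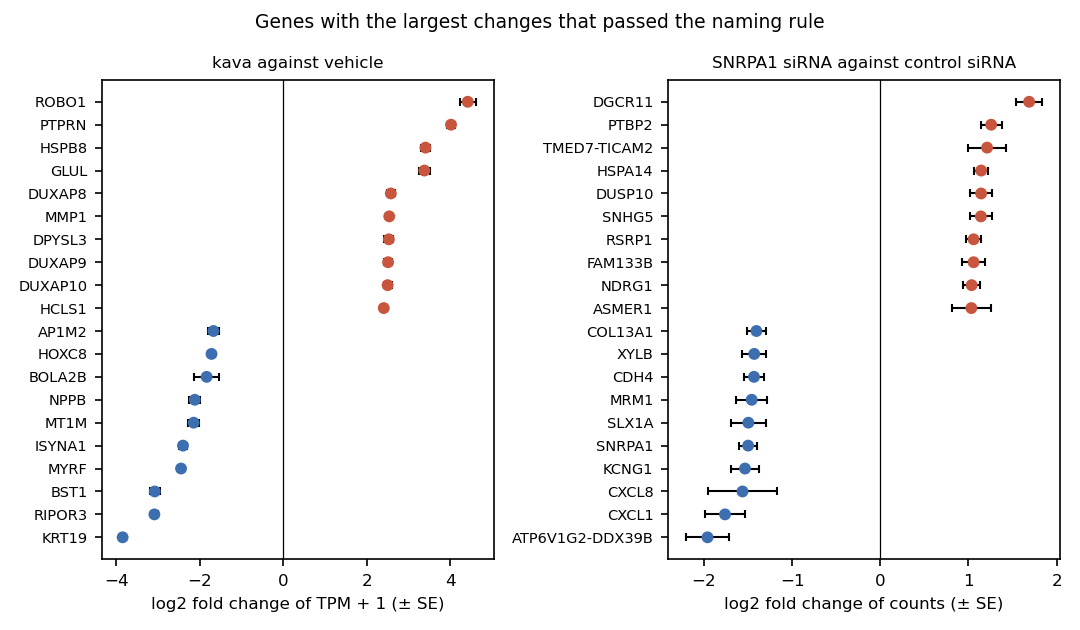
Log2 fold changes (points) with SE (bars) of the genes with the largest rises (red) and falls (blue) that passed the naming rule, for kava against vehicle (left, TPM + 1) and SNRPA1 siRNA against control siRNA (right, counts). Kava values run from -3.85 for KRT19 to 4.42 for ROBO1, and knockdown values from -1.96 for ATP6V1G2-DDX39B to 1.69 for DGCR11.

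The ATF4, NRF2, endoplasmic reticulum chaperone and lysosome lists passed upward with kava. Of 21 tested targets of ATF4 and the integrated stress response, 13 rose and 2 fell (14 and 2 adjusted over the list alone; limma camera adjusted p = 0.000173, and adjusted p = 0.268 with an estimated correlation). The secreted hormone STC2 rose from 103 ± 1.07 to 223 ± 23.9 TPM (log2 fold change 1.10), the stress regulator NUPR1 by 0.81 and the amino acid transporter SLC7A5 by 0.53, whereas ATF3 fell by 0.53. Of 25 targets of NRF2, the regulator of the antioxidant response, 12 rose and 1 fell (13 and 1 adjusted over the list alone; limma camera adjusted p = 0.000246, and adjusted p = 0.268 with an estimated correlation). They included PIR (0.94), the drug exporter ABCC3 (0.92), epoxide hydrolase EPHX1 (0.67) and the cystine transporter SLC7A11 (0.49). Of 20 endoplasmic reticulum chaperones, 10 rose and 0 fell (11 and 0 adjusted over the list alone; limma camera adjusted p = 0.000844, and adjusted p = 0.268 with an estimated correlation), among them DNAJB11 (0.61), EDEM1 (0.47), CANX (0.43) and DNAJB9 (0.34). Of 26 lysosome and autophagy genes, 13 rose and 1 fell (15 and 1 adjusted over the list alone; limma camera adjusted p = 3.78e-05, and adjusted p = 0.268 with an estimated correlation). The proteases CTSD and CTSB rose by 0.88 and 0.77, and the autophagy receptor SQSTM1 from 189 ± 5.31 to 341 ± 16.9 TPM (0.85).

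The immediate early, cholesterol and glycolysis lists also passed upward. Among 25 immediate early and cAMP-responsive genes, 14 rose and 2 fell with kava (15 and 2 adjusted over the list alone; limma camera adjusted p = 0.000186, and adjusted p = 0.268 with an estimated correlation). The phosphatases DUSP6 and DUSP4, which act on MAP kinases, rose by 0.71 and 0.63, the MAP kinase pathway inhibitor SPRY4 by 0.66 and IER3 by 0.63. Among 25 genes of cholesterol synthesis and uptake, 9 rose and 3 fell (10 and 3 adjusted over the list alone; limma camera adjusted p = 0.0137, and adjusted p = 0.315 with an estimated correlation), with STARD4 at 0.45, INSIG1 at 0.40 and squalene epoxidase SQLE at 0.30. Among 29 genes of glycolysis and the hypoxia response, 12 rose and 5 fell (14 and 7 adjusted over the list alone; limma camera adjusted p = 0.0466, and adjusted p = 0.315 with an estimated correlation). The vasodilator peptide ADM rose from 19.3 ± 1.55 to 43.3 ± 2.59 TPM (1.13). NDRG1 rose by 0.92, aldolase ALDOC by 0.85 and the lactate exporter SLC16A3 by 0.76. The call of the glycolysis list ended without vehicle replicate 3, kava replicate 1 or kava replicate 2 (limma camera adjusted p = 0.0813, 0.0660 and 0.0569).

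Of the 4 lists of splicing factors, the SR and hnRNP list and the Sm and Lsm list moved down by small amounts with kava. Of 41 SR proteins, hnRNPs and their kinases, 19 fell and 1 rose, with the same counts adjusted over the list alone (limma camera adjusted p = 0.000246, and adjusted p = 0.315 with an estimated correlation). HNRNPDL fell from 499 ± 14.001 to 399.6 ± 12.0 TPM (log2 fold change -0.32), HNRNPC and HNRNPLL each by 0.28 and the SR-like protein TRA2A by 0.27. Of 40 Sm, Lsm and other snRNP proteins, 7 fell and 1 rose (5 and 1 adjusted over the list alone; limma camera adjusted p = 0.0346, and adjusted p = 0.268 with an estimated correlation). PRPF39 fell by 0.41, USP39 by 0.21 and SNU13 by 0.20, and SNRPD3 rose by 0.48. That call ended without vehicle replicate 3, kava replicate 1 or kava replicate 2 (limma camera adjusted p = 0.0813, 0.0508 and 0.0601). Of 24 U2 snRNP and branch-site factors other than SNRPA1, 5 fell and 0 rose, also when adjusted over the list alone, and the list did not pass (limma camera adjusted p = 0.224). Its largest falls were those of SF3A3 (-0.24), SF3B1 (-0.21), the helicase DHX15 (-0.19) and DDX42 (-0.17). Of 28 Prp19 complex and catalytic-step factors, 6 fell and 4 rose (11 and 4 adjusted over the list alone; limma camera adjusted p = 0.0649), with SNW1 at -0.43, PPIL1 at -0.32, CWC22 at -0.30 and CWC27 at 0.28. The Prp19 list passed without vehicle replicate 2 or kava replicate 3 (limma camera adjusted p = 0.0494 and 0.0357). In all it passed in 4 of 17 settings of camera with its preset correlation, with a lowest adjusted p of 0.00358 (limma camera).

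The ribosomal protein, homologous recombination and G1/S lists passed downward with kava. Of 77 cytosolic ribosomal protein genes, 38 fell and 4 rose (44 and 4 adjusted over the list alone; limma camera adjusted p = 1.86e-07, and adjusted p = 0.268 with an estimated correlation). RPS29 fell by 0.64 and RPS19 by 0.29. RPL38 and RPL35A rose by 0.43 and 0.40. Of 27 genes of homologous recombination and Fanconi repair, 14 fell and 1 rose, also when adjusted over the list alone (limma camera adjusted p = 0.000382, and adjusted p = 0.315 with an estimated correlation). The checkpoint kinase CHEK2 fell from 24.7 ± 1.10 to 17.1 ± 0.382 TPM (log2 fold change -0.50), the BRCA1 partner BARD1 by 0.42, the helicase BLM by 0.39 and FANCC by 0.37. Of 36 G1/S and DNA replication genes, 15 fell and 5 rose (17 and 5 adjusted over the list alone; limma camera adjusted p = 0.0206, and adjusted p = 0.268 with an estimated correlation). Thymidylate synthase TYMS fell by 0.52 and RFC3 by 0.36. Cyclin D1, CCND1, rose from 28.9 ± 1.71 to 65.6 ± 2.75 TPM (1.16) and the transcription factor E2F1 by 0.35. Of 33 G2/M and mitosis genes, 8 fell and 4 rose (10 and 6 adjusted over the list alone; limma camera adjusted p = 0.0736), with NDC80 at -0.65, DLGAP5 at -0.51, BIRC5 at 0.36 and PTTG1 at 0.35. The mitosis list passed without kava replicate 3 (limma camera adjusted p = 0.0357). In all it passed in 3 of 17 settings of camera with its preset correlation, with a lowest adjusted p of 0.00358 (limma camera).

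The other fixed groups held genes that rose and genes that fell with kava, and did not pass camera with its preset correlation in the main test. Of 17 other settings, the p53, interferon, NF-kB and epithelial lists passed in 1 each. The heat shock list passed in 2, and the stemness and methylation lists in 3 each. In the epithelial adhesion and keratin list 8 of 21 rose and 5 fell (9 and 5 adjusted over the list alone; limma camera adjusted p = 0.121): besides the fall of KRT19, KRT7 rose from 192 ± 2.85 to 406 ± 19.0 TPM (log2 fold change 1.08) and the integrin ITGA6 by 1.03. In the mesenchymal list 9 of 28 rose and 10 fell (11 and 12 adjusted over the list alone; limma camera adjusted p = 0.963), with LOX at 0.83, TGFBI at 0.68 and TAGLN at -0.65. Its median was -0.08 while its mean was 0.03 and the direction of its test was up. In the stemness list 4 of 9 rose and 1 fell (5 and 2 adjusted over the list alone; limma camera adjusted p = 0.0637), with CD24 at 0.98, SOX9 at 0.82 and CD44 at 0.45, and the list passed without vehicle replicate 1 or kava replicate 3 (0.0474 and 0.0490). Among NF-kB and inflammatory cytokine genes 10 of 23 rose and 5 fell (11 and 5 adjusted over the list alone; limma camera adjusted p = 0.0844), with IL24 at 1.299, CSF2 at 1.00, IL1B at 0.89 and PTGS2 at 0.65. Among interferon-stimulated genes 9 of 28 rose and 4 fell (10 and 4 adjusted over the list alone; limma camera adjusted p = 0.240), with IFI44 at 0.96, OAS1 at 0.74, BST2 at -1.43 and MX2 at -0.82. Among cytosolic heat shock proteins 8 of 16 rose and 1 fell (8 and 3 adjusted over the list alone; limma camera adjusted p = 0.0736), with HSPA1A at 0.32, HSPA4 at 0.26 and HSP90AA1 at -0.28.

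Among p53 targets 6 of 27 rose and 8 fell with kava (6 and 11 adjusted over the list alone; limma camera adjusted p = 0.221), with PLK2 at 0.57, EDA2R at -1.35, TP53I3 at -0.71 and BTG2 at -0.48. Among apoptosis regulators 4 of 25 rose and 7 fell, also when adjusted over the list alone (limma camera adjusted p = 0.354), with the death receptor TNFRSF10A at 0.56, BIK at -0.68, BIRC3 at -0.43 and BMF at -0.39. Among aryl hydrocarbon receptor targets 3 of 10 rose and 1 fell (3 and 2 adjusted over the list alone; limma camera adjusted p = 0.796), with the growth factor EREG at 1.34, TIPARP at 0.35 and SERPINB2 at -0.61, and a median of -0.03 beside a mean of 0.12. Among metallothioneins and zinc transporters 2 of 7 rose and 3 fell, also when adjusted over the list alone (limma camera adjusted p = 0.509), with SLC39A10 at 0.34, SLC30A1 at 0.22 and MT1F at -0.26. Among histone and DNA methylation enzymes 2 of 28 rose and 4 fell (1 and 3 adjusted over the list alone; limma camera adjusted p = 0.0812), with KMT2D at 0.36, EED at -0.29, PRMT5 at -0.25 and TET2 at -0.24, and the list passed without vehicle replicate 2 or kava replicate 3 (0.0494 and 0.0460). In serine, folate and methionine metabolism 8 of 24 rose and 7 fell, also when adjusted over the list alone (limma camera adjusted p = 0.869), with MTHFD1 at -0.60 and SLC1A4 at 0.41. In nuclear-encoded oxidative phosphorylation 4 of 37 rose and 3 fell (2 and 2 adjusted over the list alone; limma camera adjusted p = 0.691), with NDUFB5 at 0.50, NDUFA2 at 0.35, COX6C at 0.18 and NDUFV2 at -0.46; its median was -0.02 and its mean 0.0029. Of the 28 lists, 12 passed for kava, 7 up and 5 down. With an estimated correlation camera passed 0 of them, 4 at an unadjusted p under 0.05, and fry, which does not compare a list with other genes, passed 23. Camera with an estimated correlation also has few degrees of freedom, so these losses need not come from correlation between genes.

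**Figure D3:**
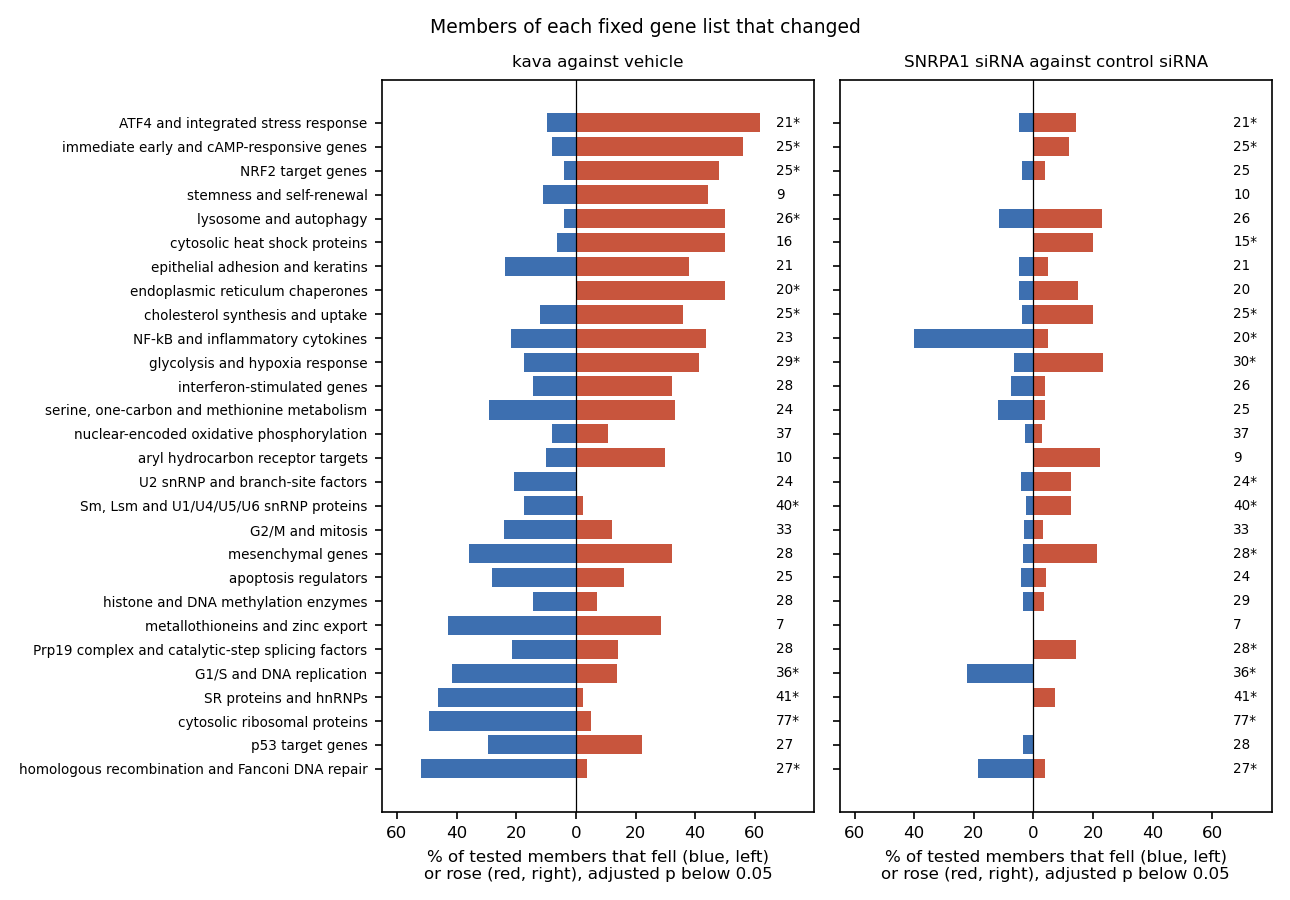
Percentage of the tested members of each fixed gene list that rose (red, right) or fell (blue, left) at an adjusted p under 0.05, for kava against vehicle and SNRPA1 siRNA against control siRNA. In the kava panel 38 of 77 ribosomal protein genes fell and 13 of 21 ATF4 targets rose, and in the knockdown panel 8 of 20 NF-kB and cytokine genes fell.

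Groups fixed as checks of RNA quality and of other cell types were measured in the same way. With kava, 1 of 13 mitochondrially encoded mRNAs fell, MT-CO1 (log2 fold change -0.17), and 0 rose, also when adjusted over the list alone (limma camera adjusted p = 0.354). Of 15 replication-dependent histone genes, 4 rose and 2 fell, also when adjusted over the list alone (limma camera adjusted p = 0.235), with H1-2 at 0.87, H2AC6 at 0.65, H2BC11 at 0.60 and H2AC20 at -1.06. Of 8 nuclear or non-polyadenylated RNAs, 2 rose and 0 fell, also when adjusted over the list alone (limma camera adjusted p = 0.297): MALAT1 rose from 291 ± 23.6 to 467 ± 132 TPM (0.65) and NEAT1 by 0.46. Of the 9 fibroblast genes, 4 were tested and 5 were too low to test. The collagen gene COL1A2 rose from 0.101 ± 0.0554 to 8.54 ± 0.378 TPM (3.12) while its partner COL1A1 fell by 0.14, from 95.4 to 86.4 TPM. THY1 stood at 388 TPM with vehicle and 397 TPM with kava, and PDGFRB at 15.9 and 18.3 TPM. Among those too low to test, COL3A1 stood at 0.0552 TPM with vehicle and 0.0233 TPM with kava. Of the blood cell genes, the macrophage marker CD68, which many cells express in lysosomes, rose by 0.88, and PTPRC stood at 0.0478 and 0.0243 TPM. Endothelial genes were too low to test, with CDH5 at 1.21 TPM with vehicle and 0.270 TPM with kava. Of the genes of differentiated airway epithelium, TUBB4B, a tubulin of most cells, was the 1 tested (0.16, limma adjusted p = 0.0605), and the secretory marker SCGB1A1 was listed at 0 in both groups.

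Changes with kava also ran along chromosomes. When tested genes were taken in order along the genome in windows of 100, 18 windows had a median log2 fold change further from that of all genes than the 95th percentile, 0.0909, of the largest window in 1000 random gene orders. On chromosome 14 from 34.9 to 102.1 Mb, 91.7% of 300 genes had lower values with kava, 204 of them fell and 8 rose, and the median was -0.35. On chromosome 3 from 129.3 to 188.2 Mb the median was 0.31, on chromosome 17 from position 60043194 to 82051831 it was 0.34, and on chromosome 5 from 43.4 to 180.1 Mb 0.24, where 273 of 500 genes rose. The start of chromosome 18, from 0.2 to 37.2 Mb, had a median of -0.25, and chromosome 22 from 15.8 to 28.8 Mb one of 0.22. Windows on chromosomes 2, 6, 8 and 11 deviated by -0.10, -0.09, 0.13 and 0.17 from the median of all genes. Other splits of the 6 libraries gave 15 to 21 windows each, with deviations of up to 0.185. Each of these splits mixes kava and vehicle libraries unequally on both sides, so part of the kava shift stays in it. Of the genes with kava values given here, PRPF39, SNW1, DLGAP5, MTHFD1, POLE2 and RPS29 lie in the chromosome 14 region and TYMS, NDC80 and NDUFV2 in that of chromosome 18. CANX, CSF2, CWC27, DPYSL3, HSPA4, LOX, NDUFA2, PLK2, PTTG1, SPRY4, SQSTM1, STARD4, STC2 and TGFBI lie in the chromosome 5 region. DNAJB11, NDUFB5 and TIPARP lie in that of chromosome 3, BIRC5, DDX42, JMJD6, RPL38 and SOX9 in that of chromosome 17, and CHEK2, DUXAP8 and SNRPD3 in that of chromosome 22. CD24, CTSD, HNRNPLL, NDRG1, NRIP3 and SQLE lie in the smaller ones. SNRPA1 lies past the last full window of chromosome 15, which ended at position 89894638, so its own region was not measured. That last window deviated by -0.0032 from the median of all genes. Over the 448 tested genes of chromosome 15, those past that window included, the median was -0.027. Other genes past the last full window of their chromosome were not placed. With all genes of the 18 shifted windows left out, an alternative chosen after seeing the data, 3231 genes changed, 1516 higher and 1715 lower, and 16 lists passed. In the main test 56.9% of the 1800 genes of these windows changed, 674 higher and 351 lower, against 28.2% elsewhere, 1587 higher and 1817 lower. The windows were picked by these same fold changes, so a larger share in them follows from the choice.

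**Figure D4:**
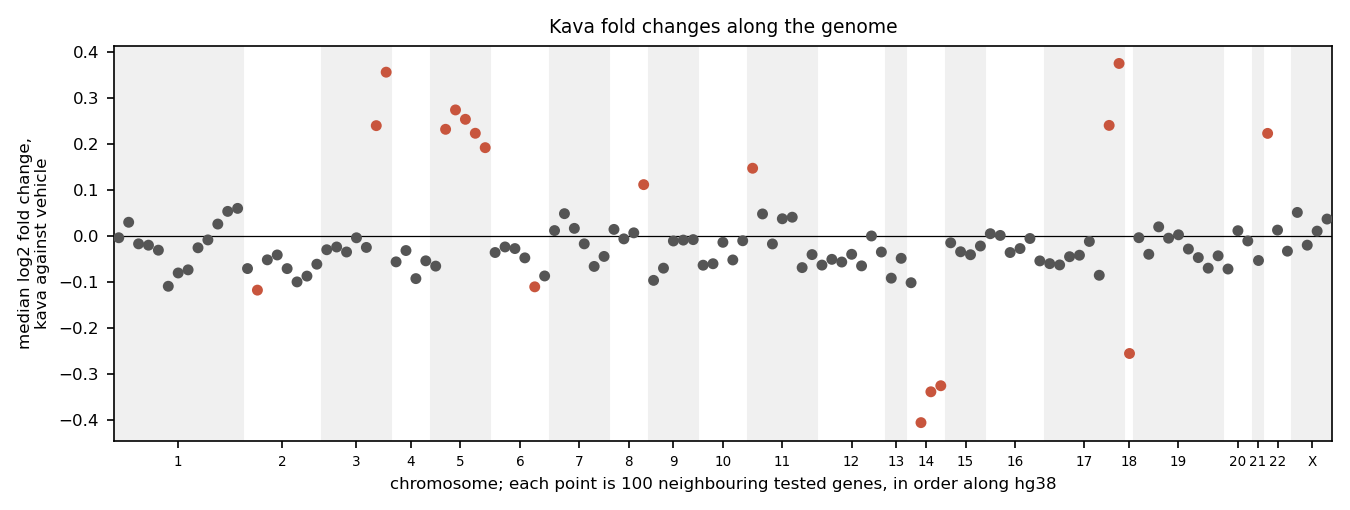
Median log2 fold change of kava against vehicle in windows of 100 neighbouring tested genes, in order along hg38; each point is a window, and coloured points are the 18 windows beyond the random gene orders. The windows of chromosome 14 from 34.9 Mb on lie lowest, with a median of -0.35 over 300 genes, and the coloured windows on chromosomes 3, 5 and 17 lie above 0.

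After SNRPA1 knockdown, the chemokine genes were among the largest falls, CXCL1 from 24.8 ± 2.99 to 7.30 ± 2.35 CPM (log2 fold change -1.76 ± 0.229, edgeR adjusted p = 0.0105) and CXCL8 from 13.9 ± 5.83 to 4.69 ± 1.95 CPM (-1.56 ± 0.387, edgeR adjusted p = 0.0439). The potassium channel subunit KCNG1 fell by 1.53, the ribose methyltransferase MRM1 of mitochondrial rRNA by 1.46, the cadherin CDH4 from 13.5 ± 0.675 to 4.99 ± 0.148 CPM (-1.43), the xylulokinase XYLB by 1.43 and the transmembrane collagen COL13A1 by 1.40. The largest rises were those of the non-coding gene DGCR11, from 3.90 ± 0.518 to 12.6 ± 0.680 CPM (1.69 ± 0.145), and of PTBP2, a splicing regulator of neurons, from 15.05 ± 1.61 to 36.0 ± 3.06 CPM (1.26 ± 0.120). HSPA14 rose from 30.8 ± 1.14 to 68.2 ± 1.60 CPM (1.15), the MAP kinase phosphatase DUSP10 by 1.14, the snoRNA host gene SNHG5 by 1.14, RSRP1 by 1.06, FAM133B by 1.06, NDRG1 by 1.04 and ASMER1 by 1.03. ATP6V1G2-DDX39B (-1.96) and TMED7-TICAM2 (1.21) are readthrough genes that share exons with their neighbours, and SLX1A (-1.496) has a near-identical copy, so their values are uncertain.

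Of 13772 tested genes, 1677 changed after the knockdown (12.2%; edgeR adjusted p under 0.05), 673 higher and 1004 lower, with a median absolute log2 fold change of 0.53 among them. At least 2-fold changes were seen in 53 genes that rose and 103 that fell. The 3 values of each group were apart in 38.7% of tested genes, where chance gives 10%. Control siRNA replicate 1 stood apart from the other control libraries, with Pearson's r across genes of 0.962 and 0.966 to them, against 0.980 between those. Left out, it gave 4546 changed genes, whereas edgeR called 0 genes without any 1 of the SNRPA1 siRNA libraries (2889 to 3267 at an unadjusted p under 0.05, and 1433 to 1948 with DESeq2), 15 without control siRNA replicate 3 and 1060 without control siRNA replicate 2. The calls of single genes given here for the knockdown are thus those of all 6 libraries. The split of 673 higher and 1004 lower became 394 and 1245 with limma on log2(FPKM + 1), and 2042 and 1905 after each library was corrected for transcript GC content and length, both chosen after seeing the data.

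The 4 lists of splicing factors passed upward after the knockdown, though most of their members did not change when tested one by one. Of 24 U2 snRNP and branch-site factors, 3 rose and 1 fell (6 and 1 adjusted over the list alone; limma camera adjusted p = 0.0315, and adjusted p = 0.250 with an estimated correlation). The helicase DDX46 rose from 88.5 ± 15.5 to 172 ± 10.7 CPM (log2 fold change 0.96), the branch-site protein SF3B6 by 0.35 and RBM17 by 0.29, while the helicase DDX42 fell from 156 ± 17.02 to 90.1 ± 4.43 CPM (-0.80). Of 40 Sm, Lsm and other snRNP proteins, 5 rose and 1 fell (7 and 2 adjusted over the list alone; limma camera adjusted p = 0.00399, and adjusted p = 0.443 with an estimated correlation), with PRPF3 at 0.76, PRPF39 at 0.69, SNRNP27 at 0.59 and PRPF31 at -0.82. Of 28 Prp19 complex and catalytic-step factors, 4 rose and 0 fell, also when adjusted over the list alone (limma camera adjusted p = 0.000515, and adjusted p = 0.134 with an estimated correlation): SLU7 (0.48), PRPF18 (0.42), SYF2 (0.42) and RBM22 (0.38). Of 41 SR proteins and hnRNPs, 3 rose and 0 fell, also when adjusted over the list alone (limma camera adjusted p = 0.00355, and adjusted p = 0.443 with an estimated correlation): TRA2A (0.40), PCBP1 (0.31) and SRSF3 (0.31). The U2 list missed the threshold without control siRNA replicate 2 or 3 (limma camera adjusted p = 0.0786 and 0.0520) and the Sm and Lsm list without control siRNA replicate 2 (0.0795). The SR and hnRNP list missed it after the correction for GC content (0.0961). The U2 list was also lost by limma on FPKM values (0.0596), with a filter on a mean CPM of 5 (0.0918) and with one on mean FPKM (0.0784). It passed in 11 of 20 settings of camera with the preset correlation, with adjusted p up to 0.198. The Sm and Lsm list passed in 18 and the SR and hnRNP list in 17.

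The NF-kB, G1/S and homologous recombination lists passed downward after the knockdown. Of 20 NF-kB and inflammatory cytokine genes, 8 fell and 1 rose (15 and 1 adjusted over the list alone; limma camera adjusted p = 2.52e-05, and adjusted p = 0.378 with an estimated correlation), with a median log2 fold change of -0.61. Besides CXCL1 and CXCL8, the cytokine IL1A fell by 1.01 and CXCL2 by 0.98. Of 36 G1/S and DNA replication genes, 8 fell and 0 rose (10 and 0 adjusted over the list alone; limma camera adjusted p = 0.00355, and adjusted p = 0.134 with an estimated correlation). The replication initiation factor CDC45 fell from 82.7 ± 8.10 to 50.6 ± 1.45 CPM (-0.71), the polymerase subunit POLA1 by 0.70, cyclin E1, CCNE1, by 0.63 and DNA ligase LIG1 by 0.61. Of 27 homologous recombination and Fanconi genes, 5 fell and 1 rose (6 and 1 adjusted over the list alone; limma camera adjusted p = 0.0257, and adjusted p = 0.532 with an estimated correlation), with FANCD2 at -0.73, FANCG at -0.57, XRCC3 at -0.46 and FANCI at -0.40. That repair list missed the threshold without control siRNA replicate 2 or 3 or SNRPA1 siRNA replicate 3 (limma camera adjusted p = 0.146, 0.0670 and 0.0511). The mitosis list did not pass, with 1 of 33 higher, TTK (0.46), 1 lower, KIF2C (-0.29), and 0 adjusted over the list alone (limma camera adjusted p = 0.727).

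A further 7 lists passed upward after the knockdown. Of 28 mesenchymal genes, 6 rose and 1 fell, also when adjusted over the list alone (limma camera adjusted p = 0.00355, and adjusted p = 0.134 with an estimated correlation). CCN2, a matrix-associated growth factor, rose from 37.9 ± 5.94 to 77.5 ± 5.99 CPM (log2 fold change 1.03), TAGLN by 0.76 and the matrix protein SPARC from 830.1 ± 48.8 to 1341 ± 39.8 CPM (0.69). Of 30 glycolysis and hypoxia genes, 7 rose and 2 fell (7 and 3 adjusted over the list alone; limma camera adjusted p = 0.00355, and adjusted p = 0.134 with an estimated correlation), with ADM at 1.01, the glucose transporter SLC2A1 at 0.62 and PFKFB4 at -0.48. Of 15 cytosolic heat shock proteins, 3 rose and 0 fell (5 and 0 adjusted over the list alone; limma camera adjusted p = 0.00399, and adjusted p = 0.139 with an estimated correlation): BAG3 (0.47), HSPA4 (0.41) and HSP90AA1 (0.35). Of 25 cholesterol genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone; limma camera adjusted p = 0.0170, and adjusted p = 0.325 with an estimated correlation), with HSD17B7 at 0.88, SC5D at 0.58, MSMO1 at 0.50 and LSS at -0.42. Of 21 ATF4 targets, 3 rose and 1 fell (6 and 2 adjusted over the list alone; limma camera adjusted p = 0.0257, and adjusted p = 0.417 with an estimated correlation), with DDIT3 at 0.62, SLC7A5 at 0.47, STC2 at 0.30 and CARS1 at -0.39. Of 25 immediate early genes, 3 rose and 0 fell, also when adjusted over the list alone (limma camera adjusted p = 0.0257, and adjusted p = 0.378 with an estimated correlation): DUSP1 (0.79), NR4A1 (0.74) and CCN1 (0.64). Of 77 ribosomal protein genes, 0 rose and 0 fell, also when adjusted over the list alone, and the list passed upward with a median of 0.08 (limma camera adjusted p = 0.0402, and adjusted p = 0.798 with an estimated correlation); RPS2 stood at 0.01 and RPLP0 at -0.16. The ATF4 list missed the threshold without control siRNA replicate 2 (limma camera adjusted p = 0.108) or SNRPA1 siRNA replicate 3 (0.0502), and the immediate early list without control siRNA replicate 1 (0.0813) or 3 (0.0510). The ribosomal list was lost without control siRNA replicate 3 (limma camera adjusted p = 0.463), SNRPA1 siRNA replicate 2 (0.0608) or 3 (0.164), or control siRNA replicate 2 (0.953), which also turned its direction, with a median of -0.04. After the correction for GC content it missed the threshold as well (0.0879). The immediate early list was also lost by limma on FPKM values (0.175) and with filters on a mean CPM of 5 (0.0672) or on mean FPKM (0.0784). These filters also ended the call of the ATF4 list (0.0682 and 0.0784). The cholesterol list was lost by limma on FPKM values (0.0719). Of 20 settings, the immediate early and ribosomal lists passed in 11 each and the ATF4 and cholesterol lists in 15 each. Their adjusted p reached 0.282, 0.953, 0.194 and 0.251 (limma camera).

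The remaining lists did not pass camera with its preset correlation in the main test of the knockdown. Of 26 lysosome and autophagy genes, 6 rose and 3 fell (6 and 4 adjusted over the list alone; limma camera adjusted p = 0.622), with GABARAPL1 at 0.59, BECN1 at -0.67, ATG7 at -0.65 and WIPI1 at -0.58. Of 20 endoplasmic reticulum chaperones, 3 rose and 1 fell, also when adjusted over the list alone (limma camera adjusted p = 0.146), with HERPUD1 at 0.42, DNAJB11 at 0.31, PDIA4 at 0.27 and HYOU1 at -0.46. Of 25 serine, folate and methionine genes, 1 rose and 3 fell (1 and 5 adjusted over the list alone; limma camera adjusted p = 0.348), with ODC1 at 0.36, SHMT1 at -0.48, AHCY at -0.47 and MTHFD1L at -0.45. Of 26 interferon-stimulated genes, 1 rose and 2 fell, also when adjusted over the list alone (limma camera adjusted p = 0.676), with RIGI at 0.60, IFI35 at -0.65 and OAS3 at -0.50. Of 25 NRF2 targets, 1 rose, UGDH (0.50), and 1 fell, ABCC3 (-0.50), and of 9 aryl hydrocarbon receptor targets 2 rose, NFE2L2 (0.49) and SLC7A5, and 0 fell, with the same counts adjusted over the list alone for both (limma camera adjusted p = 0.348 and 0.285). Of 24 apoptosis regulators, 1 rose, BCL2L1 (0.48), and 1 fell, BCL2L2 (-0.73), with 2 and 2 adjusted over the list alone (limma camera adjusted p = 0.0710). Of 21 epithelial genes, 1 rose, KRT17 (0.80), and 1 fell, PKP3 (-0.60); of 29 methylation enzymes, 1 rose, KMT5A (0.49), and 1 fell, DNMT1 (-0.47); and of 37 oxidative phosphorylation genes, 1 rose, NDUFC2 (0.45), and 1 fell, UQCRC2 (-0.59). These counts were the same adjusted over the list alone (limma camera adjusted p = 0.676, 0.498 and 0.722). Of 28 p53 targets, 1 fell, DDB2 (-0.42), and 0 rose, also when adjusted over the list alone (limma camera adjusted p = 0.298). Of 7 metallothioneins and zinc transporters and 10 stemness genes 0 changed, also when adjusted over the list alone (limma camera adjusted p = 0.348 and 0.354), with MT2A at 0.02, MT1E at 0.18, CD44 at 0.16 and MYC at -0.08. Without control siRNA replicate 1 the NRF2, apoptosis and oxidative phosphorylation lists passed upward (limma camera adjusted p = 0.0490, 0.0490 and 0.00484). Of 20 settings of camera with its preset correlation, the apoptosis list passed in 6 and the endoplasmic reticulum chaperone list in 1. Their lowest adjusted p was 0.0129 and 0.0187 (limma camera). In all, 14 of 28 lists passed for the knockdown, 11 up and 3 down. With an estimated correlation camera passed 0, 5 at an unadjusted p under 0.05, and fry passed 13, among them the apoptosis, p53 and endoplasmic reticulum chaperone lists. Here too, the few degrees of freedom of camera with an estimated correlation leave the cause of its lost calls open.

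The check groups of the knockdown were as follows. Of 13 mitochondrially encoded mRNAs, 1 rose, MT-ND5, from 2280.5 ± 226 to 3039.6 ± 118 CPM (log2 fold change 0.41), and 0 fell (2 and 0 adjusted over the list alone; limma camera adjusted p = 0.0226, and adjusted p = 0.714 with an estimated correlation). With quantile-normalised FPKM values the log2 fold change of MT-ND5 was -0.0843. Of 10 histone genes 0 changed, also when adjusted over the list alone (limma camera adjusted p = 0.847), with H2BC12 at 0.28 and H1-2 at 0.07, and of 5 nuclear or non-polyadenylated RNAs 1 fell, NEAT1 (-0.46), and 0 rose, also when adjusted over the list alone (limma camera adjusted p = 0.906). Their median of -0.46 and mean of -0.18 stood beside an upward direction of the list test. COL1A1 rose by 0.38 and CD68 fell by 0.88, while CDH5 (-0.20) and TUBB4B (-0.21) did not pass (edgeR adjusted p = 0.691 and 0.257).

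Of 12295 genes with a symbol tested in both experiments, 151 were higher with kava and after the knockdown, where 107.5 are given by independent lists (Fisher's exact test, two-sided, odds ratio 1.57, 95% interval 1.29 to 1.91, adjusted p = 2.37e-05 over 4 tests). They included ADM (1.13 with kava and 1.01 with knockdown), NDRG1 (0.92 and 1.04), the phosphatase DUSP10 (0.91 and 1.14), JMJD6 (0.74 and 0.69), the urokinase receptor PLAUR (0.66 and 0.79), MMP24 (0.75 and 0.66), the cytokine IL18 (0.78 and 0.64) and NRP1 (0.66 and 0.63). Lower in both were 168 genes against 163.9 (odds ratio 1.03, 95% interval 0.863 to 1.23, adjusted p = 0.721 by Fisher's exact test), among them the glycine decarboxylase GLDC (-1.29 and -0.93), COL27A1 (-0.89 and -1.13), RAPGEFL1 (-0.76 and -0.81), TNFRSF9 (-0.68 and -0.95), complement factor CFB (-0.68 and -0.64), the polymerase subunit POLE2 (-0.78 and -0.63), SLC13A3 (-0.63 and -1.59), CPNE7 (-0.62 and -1.11) and PLEKHG4B (-1.28 and -0.62). FAM86B1 (-0.69 and -1.31) belongs to a family of close copies and is uncertain. Opposite changes were found in 269 genes against 271.6, such as NPPB (-2.12 and 1.44), CORO2B (1.12 and -1.34), CDH4 (1.03 and -1.43), COL13A1 (0.99 and -1.40) and NRIP3 (0.97 and -0.93). The genes tested in both are not independent replicates, so the p-values and intervals of Fisher's exact test do not measure the spread between libraries. Across all of these genes, fold changes had a Pearson's r of -0.0061 and a Spearman's rho of 0.0075. The experiments share no library. With 1 siRNA library left out, 0 to 840 genes changed the same way, and 0 to 401 were higher in both. With all libraries kept, 298 genes were higher in both after the GC correction, against 242 for independent lists. Pseudocounts of 0.1 and 0.5, with limma on FPKM for the knockdown, gave 93 each against 60.5 and 61.0. Without trend, also on FPKM, the count was 76 against 51.7, and without a filter 43 against 22.6. Without control siRNA replicate 1, 401 genes were higher in both against 362 for independent lists. Lower in both were 439 against 381. After the GC correction, genes lower in both also exceeded the number for independent lists (281 against 245). Without a filter they did so too (59 against 31.7), with 82 genes changed in opposite directions. Leaving out the filter adds low genes that are rarely called, which lowers the number for independent lists. The excess without a filter, also of genes higher in both, thus carries no weight.

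**Figure D5:**
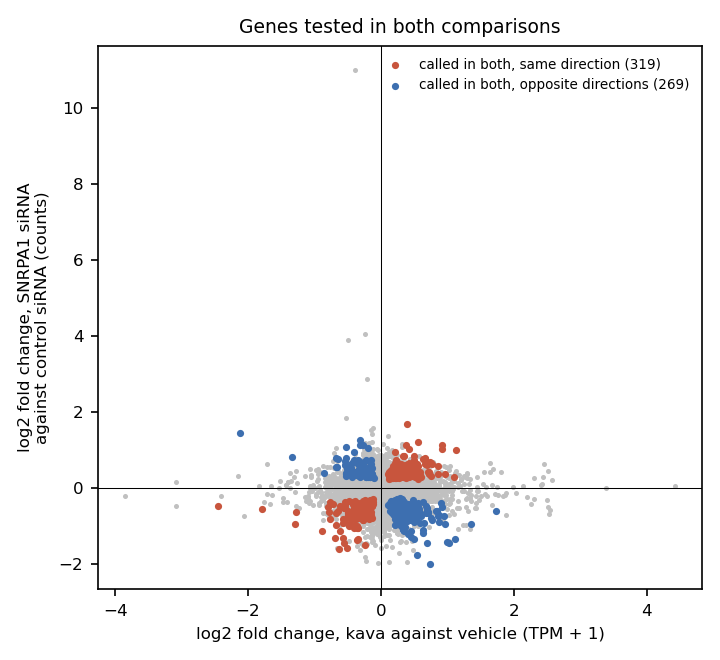
Log2 fold change of each gene tested in both experiments, with kava against vehicle (TPM + 1) on the horizontal axis and SNRPA1 siRNA against control siRNA (counts) on the vertical axis. Red points are the 319 genes that changed in the same direction in both, blue points the 269 that changed in opposite directions, and grey points all others; Pearson's r across genes is -0.0061.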

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

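DESeq2, limma on log2(FPKM + 1), a filter on mean FPKM, the GC and length corrections and the removal of shifted chromosome windows were chosen after seeing the data. The other alternatives were planned before the data were examined.

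For kava, SNRPA1 was lower and called in all alternatives that tested it. Among named genes and lists called in the main test or in the alternative, 0 changed direction. Changes of direction without a call in either were not counted. The number of changed genes lay between 3155 and 4312 with 1 library left out and was 3954 with the replicate number as a block (replicate block), where SNRPA1 stood at -0.24 (limma adjusted p = 0.0109). The number lower lay between 1400 and 2099 with 1 library left out, lowest without vehicle replicate 1. Without a filter 3614 genes changed and 19 lists passed. A required log2 fold change of at least 1 left 208 genes, 151 higher and 57 lower. Of the 28 lists, 0 passed camera with an estimated correlation in limma (4 at an unadjusted p under 0.05) and 23 passed fry. Of the 12 passing lists, 10 passed in each of the 17 settings of camera with its preset correlation. The Sm and Lsm list and the glycolysis list passed in 12 each, with adjusted p from 0.000739 to 0.0813 and from 0.0281 to 0.0854 (limma camera).

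For the knockdown, SNRPA1 kept its direction in all alternatives, with log2 fold changes from -1.556 to -1.436 by edgeR with 1 library left out. The number of changed genes then lay between 0 and 4546, with 0 to 2222 higher and 0 to 2324 lower, and the number of passing lists between 9 (without control siRNA replicate 2) and 16. The 0 belongs to each SNRPA1 siRNA library in turn by edgeR, with 2992, 2889 and 3267 genes at an unadjusted p under 0.05 and 1622, 1433 and 1948 called by DESeq2. DESeq2 called 3195 genes with all libraries, 1427 higher and 1768 lower, including all 1677 called by edgeR. It called 5376 without control siRNA replicate 1 (2808 higher, 2568 lower) and 3008 without replicate 2 (1400 and 1608), and 524 to 2808 higher and 909 to 2568 lower with 1 library left out. With the replicate block edgeR called 0 genes, 0 higher and 0 lower, with 2919 at an unadjusted p under 0.05, and SNRPA1 stood at -1.498 (edgeR adjusted p = 0.118). The labels do not say that the replicate numbers pair the samples. Residuals of libraries with the same number correlated at -0.30, 0.06 and -0.12, and those with different numbers between -0.194 and 0.253. With 3 libraries in each group, these values cannot settle whether samples were paired. Without a filter 669 genes changed, 258 higher and 411 lower, with more genes tested. The GC correction gave 2955 genes, 1474 of them higher, and that for GC and length 3947, 2042 higher and 1905 lower. On FPKM limma called 394 higher genes, 382 and 386 with pseudocounts of 0.1 and 0.5, and 365 without trend. Quantile-normalised FPKM values left 3 lists and turned MT-ND5 to -0.0843. The median of the ribosomal list lay between -0.0378 (without control siRNA replicate 2, where it turned) and 0.304 (without control siRNA replicate 1). A required log2 fold change of at least 1 left 156 genes, 53 higher and 103 lower. Camera with an estimated correlation in limma passed 0 lists (5 at an unadjusted p under 0.05). The Prp19, G1/S and NF-kB lists passed in each of the 20 settings of camera with its preset correlation. The heat shock, glycolysis and mesenchymal lists passed in 19 each, lost with quantile-normalised FPKM values. The homologous recombination list passed in 16, with adjusted p up to 0.146 (limma camera). Where no reason is given, the cause was not tested.

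The 319 genes changed the same way in both comparisons became 102 without a filter, 0 with the replicate block by limma and edgeR, 579 with the GC correction, and 0 to 840 with 1 library left out, as the number of knockdown calls moved. Pearson's r across genes stayed between -0.0207 and 0.0156. The depth of the TPM table is unknown, and in simulated data the knockdown test recovered 4.48% of 67 changes of 0.5 on the log2 scale. Those data held far fewer changed genes than were called here, so the share does not carry over to the measured libraries, where the median absolute log2 fold change of the called genes was 0.53.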

Other observations

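Gene Ontology terms, the test of the chromosome windows after removal of the GC trend, and the count of windows in other splits were chosen after the results were seen. The chromosome windows and the tests of transcript features were set after the data were examined but before their own results were seen, and the splits of the genes, lists and overlap were planned before.

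Gene Ontology terms of ribosome assembly moved down with kava. Of 70 genes of ribosomal small subunit biogenesis, 35 fell and 3 rose (limma camera adjusted p = 1.77e-05). This call and those of all terms below for kava were lost with an estimated correlation (limma camera adjusted p = 0.887 for each, and 0 of 1267 terms passed, with 53 at an unadjusted p under 0.05). The loss need not come from correlation between genes, since that setting also has few degrees of freedom. Of 20 genes of purine nucleotide biosynthesis 12 fell and 1 rose, and of 20 circadian rhythm genes 11 fell and 1 rose (limma camera adjusted p = 0.00295 for each). Secretory pathway terms moved up: of 63 genes of the membrane of the intermediate compartment between endoplasmic reticulum and Golgi, 28 rose and 5 fell (limma camera adjusted p = 0.000883), and of 59 lysosomal lumen genes 28 rose and 7 fell (0.00295). Of 17 genes of ascorbic acid binding 9 rose and 0 fell (0.00295), of 27 genes of TGF-beta receptor signalling 14 rose and 3 fell (0.0291), and of 53 proteasome genes 20 rose and 8 fell (0.0474). In all, 55 of 1267 terms passed, 25 up and 30 down.

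After the knockdown, 12 of 1308 terms passed, 7 up and 5 down, and all of these calls were lost with an estimated correlation (limma camera adjusted p = 0.998 for each term given here for the knockdown, and 0 terms passed, with 47 at an unadjusted p under 0.05). The same limit in degrees of freedom holds for these terms. Of 21 genes of amino acid metabolism 9 fell and 0 rose (limma camera adjusted p = 0.000652), and of 111 ligase genes 21 fell and 2 rose (0.0394). Of 266 RNA splicing genes 35 rose and 9 fell (limma camera adjusted p = 0.00184), and of 163 genes of the spliceosomal complex 20 rose and 5 fell (0.0106). The response to mechanical stimulus passed upward in both comparisons, with 10 of 17 genes higher and 1 lower with kava (limma camera adjusted p = 0.00402) and 4 higher and 0 lower after the knockdown (0.0394).

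Kava fold changes shifted together along chromosomes in 18 windows, with a permutation p of 0.000999, the smallest that 1000 random gene orders can give, and a candidate explanation is a difference in copy number, or in the mix of clones, between the kava and vehicle cultures. The medians on chromosomes 14, 3, 5 and 17 were -0.35, 0.31, 0.24 and 0.34. Log2 ratios of whole copies are -0.42 for a loss from 4 copies to 3 and 0.58 for a gain from 2 to 3. The medians lie between these, but so does 0, so this is no support for a change in copy number. Those of chromosomes 3 and 5 lie under the 0.32 of a gain from 4 copies to 5. All 3 kava libraries showed the shift on chromosome 14. Differences in GC content between the libraries are argued against as the whole cause, since 88.9% of the windows stayed beyond the random orders after the GC trend was taken out. Random gene orders alone do not set kava apart, since the knockdown had 5 windows beyond its own limit of 0.154 with the same permutation p of 0.000999. In 3 of the 10 splits of the kava and vehicle libraries, too few for a share under 0.05, at least 18 windows were found. The highest other count was 21, though with deviations of at most 0.185 against 0.393. Each other split mixes kava and vehicle libraries unequally on both sides, so part of the kava shift stays in it. These counts thus do not show what libraries without a kava difference would give. DNA was not analysed here, and whether kava, clonal drift over 20 weeks or both led to the shift stays open, as does the part of the lists that it moves.

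Knockdown fold changes followed transcript GC content, with a Spearman's rho across genes of -0.292. A GC bias between libraries may account for this, since another split of the 6 libraries gave a rho 1.94 times as large in size (0.565). For a loss of genes with short introns, the partial correlation with intron length, given GC and length, was 0.0287. Other splits of the libraries gave 0.0686 to 0.186, all larger, so this measure cannot decide the question. Without regard to GC and length, the median log2 fold change was -0.07 in the fifth of genes with the shortest introns. It was 0.04 in the fifth with the longest. The siRNA is the biological difference named by the design, and its own effect on GC-rich genes stays open.

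Control siRNA replicate 1 stood apart from the other control libraries, and its deviation from them followed transcript length (Spearman's rho across genes of -0.531) and GC content (0.564). Control siRNA replicates 2 and 3 gave 0.489 and 0.394 for length and -0.535 and -0.410 for GC content, but each was measured against a mean that holds replicate 1. In the SNRPA1 siRNA libraries, measured against each other, the values were 0.286, -0.0591 and -0.256 for length and -0.462, 0.0837 and 0.415 for GC content. Either bias may contribute to its distance, but what sets it further apart than the other libraries stays open, and length and GC content were not told apart. No biological explanation was tested.

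Other splits of the 6 libraries of each comparison give at most 10 results, too few for a share under 0.05. The real split had the most changed genes in both, 1 of 10 splits, with 4429 against at most 1 for kava and 1677 against at most 4 for the knockdown. It also had the most passing lists, 1 of 10 splits, but by a narrow margin, with 12 against at most 11 for kava and 14 against at most 13 for the knockdown. Each other split mixes the compared groups unequally on both sides, so part of the real difference stays in it. Its list count thus does not show what libraries without a difference would give. For the correlation of fold changes between the comparisons, 89 of 100 relabelled pairs of splits gave an absolute Pearson's r at least as large as that of -0.0061, and the highest was 0.162. For the 319 genes changed the same way, 1 of 100 pairs gave as many, the real one, and the highest other count was 1. The other splits call at most 4 genes in either comparison, so no relabelled pair could reach that count, and this test says nothing about whether the lists depend on each other.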
